A study of Mus musculus with 4 samples.

How the data were processed

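Circular chromosome conformation capture with sequencing (4C-seq) was carried out on 4 libraries from C57BL/6 mouse cells, 2 from an embryonic stem (ES) cell line and 2 from a trophoblast stem (TS) cell line, with the promoter of Tead4 as the bait. 4C-seq reads out which restriction fragments of the genome were ligated to 1 chosen fragment after cross-linking. Per the labels' protocols, cross-linked chromatin was cut with HindIII, the overhangs were filled in, the ends were ligated in dilute solution, and the product was cut with MspI, ligated again and amplified with a primer pair on the Tead4 promoter. The libraries were grouped by the cell type and replicate number in their titles. Nothing in the labels says whether replicates came from separate cultures, so the spread between them may be technical.

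Per the submitters' processing notes, base calling used CASAVA 1.8.1, and BWA and the mouse build mm9 were used. The BWA version, the rule that assigned reads to fragments, any mapping quality filter and the treatment of duplicate reads are not given in the sources used here. The deposited values are raw read counts per HindIII fragment, 1 file per library, with no normalisation. Each file lists the fragments with at least 1 read, and a fragment that a file does not list was taken as 0 reads. A further deposited file lists all 842110 HindIII fragments of mm9, and its score column, per the values of the deposited file, is the fragment length divided by 100, rounded down and capped at 1000, for 842110 of 842110 fragments. Adjoining fragments in that list overlap by the HindIII site. Coordinates are given 1-based in mm9.

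Total reads were 5339767 and 3997337 in ES replicates 1 and 2 and 740750 and 2931918 in TS replicates 1 and 2. The widest exact (Clopper-Pearson) 95% interval of a share of reads was 0.225 percentage points. A fragment with 0 reads was given a limit of 3 reads, which is 0.562 and 0.751 reads per 1000000 (rpm) in ES replicates 1 and 2 and 4.05 and 1.02 rpm in TS replicates 1 and 2. PCR reads without molecular identifiers are not independent molecules, so these intervals and limits cover counting error only.

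The tests of the share on the bait chromosome and of the overlaps, the count of fragments specific to TS, the edgeR comparison and the rule for the named regions were fixed before the data were examined. The test of fragments within 1 Mb was added afterwards. The background was the 838652 HindIII fragments on the 21 chromosomes and contigs with a listed fragment. The share of listed fragments on the bait chromosome was tested with a two-sided Fisher's exact test, and the overlap of 2 lists with a one-sided Fisher's exact test, each with Benjamini-Hochberg adjustment within its family. These tests treat fragments as independent and compare libraries, not conditions. With 2 libraries per cell type, an exact permutation test of a difference between ES and TS cannot give p below 0.333. Read counts were also compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, TMM normalisation, filterByExpr), in which 18 of the 421 fragments listed in any library passed the filter. That test had been set down for files that list every fragment. It was run because the files go down to 1 read, with unlisted fragments taken as 0. DESeq2 1.42.0 was an alternative. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

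The overlap test was tested on simulated lists of 100 and 150 fragments drawn from the 838652 background fragments. It called 1 of 100 pairs of lists with no planted overlap and 100 of 100 with 5 planted fragments. The edgeR script was tested on counts simulated for the 421 fragments with 2 libraries per cell type. Shares called are of the changed fragments that passed the filter, and changed fragments that did not pass are not counted. With a dispersion of 0.1 it called 31 of 46 fragments changed 4-fold (67.4%) and 46 of 46 changed 16-fold (100%). It also called 0 unchanged fragments in the 4-fold run and 2 in the 16-fold run. With the dispersion of 9.73 estimated from the deposited counts it called 0 of 23 fragments changed 4-fold and 0 of 32 changed 16-fold.

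The files do not mark the bait's own fragment, and no mm9 genome or annotation was used here. Distances were therefore measured from a reference position on chromosome 6, the bait's chromosome, set after seeing the data at the centre (128242688) of the 25 kb stretch with the most entries over all libraries. That stretch spans 128232142 to 128253234 and holds 4 listed fragments with 12 entries. The gene table used here (NCBI RefSeq, GRCm38.p6) is on another build, so its coordinates were not used and no fragment was given a gene name. The planned test of gene lists (trophoblast, pluripotency and feeder fibroblast genes, and the neighbours of Tead4) was not run for this reason. The text names every fragment within 1 Mb of the reference position, every fragment listed in both replicates of a cell type or in at least 3 libraries (at most 20), and the 5 fragments with most reads in each library outside 1 Mb. This gave 29 fragments. The part of the rule that needs gene positions named none.

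Alternatives set beforehand were keeping only fragments above a list's median read count, merging fragments within 10 kb, counting fragments within 10 or 100 kb as shared, leaving out the region within 1 Mb of the reference position or the whole bait chromosome, a background of fragments of 500 bp or longer, leaving out each library, a replicate block, DESeq2 and no filter on low counts. Added after seeing the data were minimum counts of 10 and 100 reads, leaving out the Y_random contig (unplaced Y chromosome sequence in mm9) or the fragments listed in every library, and a partner-read filter. That filter drops a fragment from a library where it has fewer reads than 1 in 1000 of its count in the library of the other cell type with the same replicate number.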

Results

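Tead4 encodes a TEAD-family transcription factor required for the trophectoderm, the outer layer of the blastocyst. ES cells derive from the inner cell mass and TS cells from the trophectoderm, and the series compared which genomic regions contact the Tead4 promoter in each. The data were read counts per HindIII fragment in 2 ES and 2 TS 4C-seq libraries. The libraries held 5339767 and 3997337 reads (ES replicates 1 and 2) and 740750 and 2931918 reads (TS replicates 1 and 2). Tead4 lies on chromosome 6, between Tspan9 and Tulp3 in the GRCm38 gene order, with Rhno1 and Foxm1 beyond Tulp3.

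Reads were concentrated on few fragments in all 4 libraries. The lists hold every fragment with at least 1 read, and no test separated contacts of the bait from other sources of reads. ES replicate 1 listed 105 fragments, ES replicate 2 listed 185, TS replicate 1 listed 64 and TS replicate 2 listed 153, and 421 different fragments were listed in all. The single most abundant fragment held 25.7% of the reads in ES replicate 1, 81.5% in ES replicate 2, 42.2% in TS replicate 1 and 67.5% in TS replicate 2. The 3 most abundant held 78.3% ± 25.3 of the reads in ES (SD, n = 2) and 84.5% ± 11.2 in TS (SD, n = 2). Fragments with a single read made up 65.4% and 67.3% of the lists in ES and TS replicate 2, against 25.7% and 14.1% in ES and TS replicate 1. With a minimum of 100 reads, 38 and 19 fragments remained in ES replicates 1 and 2 and 19 and 13 in TS replicates 1 and 2.

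Fragments of the bait's own chromosome were over-represented in the list of every library. Chromosome 6 held 12 of 105 listed fragments in ES replicate 1 (11.4%, exact 95% interval 6.05 to 19.1%) and 21 of 185 in ES replicate 2 (11.4%, 7.17 to 16.8%). It held 16 of 64 in TS replicate 1 (25%, 15.0 to 37.4%) and 18 of 153 in TS replicate 2 (11.8%, 7.12 to 18.0%). Chromosome 6 holds 5.68% of the background fragments. The adjusted p of Fisher's exact test was 0.0183 and 0.00457 for ES replicates 1 and 2, and 1.65e-06 and 0.00549 for TS replicates 1 and 2. The mean share was 18.4% ± 9.36 in TS and 11.4% ± 0.0546 in ES (SD, n = 2 each), and the exact two-sided permutation p of 0.333 is the smallest that 2 libraries per group allow. The difference of 6.99 percentage points was 0.375 without TS replicate 1 and 13.6 without TS replicate 2. The share was higher with a minimum count than without in all 4 libraries. With at least 10 reads it was 15.1% and 32% in ES replicates 1 and 2 and 38.7% and 38.9% in TS replicates 1 and 2, and with at least 100 reads 18.4% and 31.6% in ES and 47.4% and 38.5% in TS, so the closeness of the ES shares held only for the full lists. Without the fragments within 1 Mb of the reference position, no library kept its call at an adjusted p under 0.05 (Fisher's exact test): the share was 5.10% in ES replicate 1 (adjusted p = 1.0), 9.39% in ES replicate 2 (adjusted p = 0.0691), 14.3% in TS replicate 1 (adjusted p = 0.05004) and 8.78% in TS replicate 2 (adjusted p = 0.14). The partner-read filter, which drops fragments with under 1 in 1000 of their reads in the same-number library of the other cell type, lowered it to 8.82% in ES replicate 1 (adjusted p = 0.192).

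The share of reads on chromosome 6 followed the replicate number more than the cell type. It was 37.6% in ES replicate 1 and 20.4% in TS replicate 1, but 1.84% in ES replicate 2 and 2.12% in TS replicate 2. The means were 19.7% ± 25.3 in ES and 11.2% ± 12.9 in TS (SD, n = 2 each), a difference smaller than the spread between replicates (exact permutation p = 1.0). In the ES libraries nearly all of these reads lay within 1 Mb of the reference position, 2006053 of 2008559 in replicate 1 and 66646 of 73460 in replicate 2. In TS replicate 1 the figure was 122179 of 150827. In TS replicate 2 it was 141 of 62159, with 33448 reads on 4 fragments between 1 and 10 Mb away and 28570 on 9 fragments farther away.

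Near the reference position, 2 fragments were abundant in both ES libraries and scarce or unlisted in both TS libraries. The files do not mark the bait's own fragment, so it is not known whether either of them is that fragment, uncut or ligated to itself, in place of a contact. H641130 (chromosome 6, 128237571 to 128248349) had 183235 and 27375 reads in ES replicates 1 and 2, 2 reads in TS replicate 1 and 0 in TS replicate 2. H641132 (128248429 to 128251380) had 146505 and 13608 reads in the ES libraries, 9 in TS replicate 1 and 0 in TS replicate 2. In reads per 1000000 reads of the library (rpm), H641130 was at 20582 ± 19422 in ES and 1.35 ± 1.91 in TS (SD, n = 2 each). H641132 was at 15420 ± 16993 in ES and 6.07 ± 8.59 in TS (SD, n = 2 each). Against TS replicate 1, H641130 was 12710-fold higher in ES replicate 1 (exact 95% counting interval 3518 to 104947) and 2536-fold higher in ES replicate 2 (702 to 20945). H641132 was 2258-fold (1190 to 4939) and 280-fold (148 to 613) higher. Against the limit of 3 reads in TS replicate 2, H641130 was at least 33537-fold and at least 6693-fold higher in ES replicates 1 and 2, and H641132 at least 26814-fold and at least 3327-fold higher. These ratios compare amplified libraries and carry no replicate error. The 2 and 9 reads of TS replicate 1 equal 10.9 and 61.4 per 1000000 reads of the same fragments in ES replicate 1. Over the 18 fragments with at least 10000 reads in 1 library and under 1 in 1000 of that in the library of the same number, this ratio ranged from 2.27 to 194.7. H641130 and H641132 are 2 of these 18, so their place within the range is fixed and is no test. The adjacent H641133 (128251375 to 128253234) had 317 and 12 reads in ES, 0 in TS replicate 1 and 1 in TS replicate 2. H641127 (128232142 to 128236425) had 301916 reads in ES replicate 1 and 0 in ES replicate 2, with 3 and 91 reads in TS replicates 1 and 2. These 4 fragments define the reference stretch, so their abundance near the reference position is not an independent result.

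None of the 18 fragments tested passed edgeR's quasi-likelihood test at an adjusted p under 0.05, and 0 had an unadjusted p under 0.05. The adjusted p was 0.37 for both H641130 and H641132, whose exact permutation p of 0.333 is the smallest possible with 2 libraries per group. DESeq2 called 11 of the 18 lower in TS and 0 higher. Of these 11, H641130 and H641132 held at least 100 reads in both ES libraries, and the other 9 did so in 1 ES library only. The filter favoured fragments abundant in ES, because 3 reads in TS replicate 1 were already 4.05 rpm. H226562, with 54795 reads in ES replicate 1 and 3 in TS replicate 1, was tested. H641034 (56403 reads in TS replicate 1, 2 in ES replicate 1) and H211826 (440437 in TS replicate 2, 1 in ES replicate 2) were not. The direction of the 11 calls therefore partly reflects which fragments were tested. The TMM factors ranged from 0.0918 (ES replicate 2) to 4.45 (TS replicate 1), so the scaling between libraries is itself uncertain. DESeq2's default scaling uses only fragments with reads in every library, here the 3 listed in all 4 libraries. Of these, H690798 varied 247-fold in reads between libraries and H125346 363-fold. The 11 DESeq2 calls and their direction therefore also depend on a scaling set by these 3 fragments.

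Farther out within 1 Mb, ES replicates 1 and 2 and TS replicate 1 each listed their own abundant fragments, while TS replicate 2 listed none above 42 reads. No test separated cell type from library. In ES, H641103 (128140766 to 128143225) held 1374076 reads in replicate 1 and 0 in replicate 2, and H641114 (128166545 to 128173228) held 25651 in replicate 2 and 0 in replicate 1. In the TS libraries H641103 had 50 reads in replicate 1 and H641114 had 3 in replicate 2. In TS replicate 1, H641034 (127896638 to 127901458) held 56403 reads, H641101 (128138740 to 128140274) 48032, H640993 (127720475 to 127723296) 10480 and H641162 (128373176 to 128375624) 7200. Of these, H641034 and H641101 had 2 reads each in ES replicate 1, and TS replicate 2 listed none of the 4. H641101 in TS replicate 1 and H641103 in ES replicate 1 are 491 bp apart. TS replicate 2 listed H641086 (128091980 to 128095536) with 42 reads and H641058 (128008103 to 128010495) with 4. Fragments within 1 Mb made up 7 of 12, 4 of 21, 8 of 16 and 5 of 18 chromosome 6 fragments in ES replicates 1 and 2 and TS replicates 1 and 2, against 1.23% of the background on the chromosome. This test was chosen after the data were seen. With the 4 reference fragments left out, Fisher's exact test (one-sided) gave an adjusted p of 0.000195 in ES replicate 1 (3 of 8 fragments), 1.27e-06 in TS replicate 1 (5 of 13), 0.00121 in TS replicate 2 (3 of 16) and 0.199 in ES replicate 2 (1 of 18). The ES replicate 1 call rests on H641034 and H641101, with 2 reads each. With the partner-read filter it was lost (1 of 5, adjusted p = 0.0796), while the adjusted p was 4.05e-05 in TS replicate 1 and 0.0282 in TS replicate 2.

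**Figure D1:**
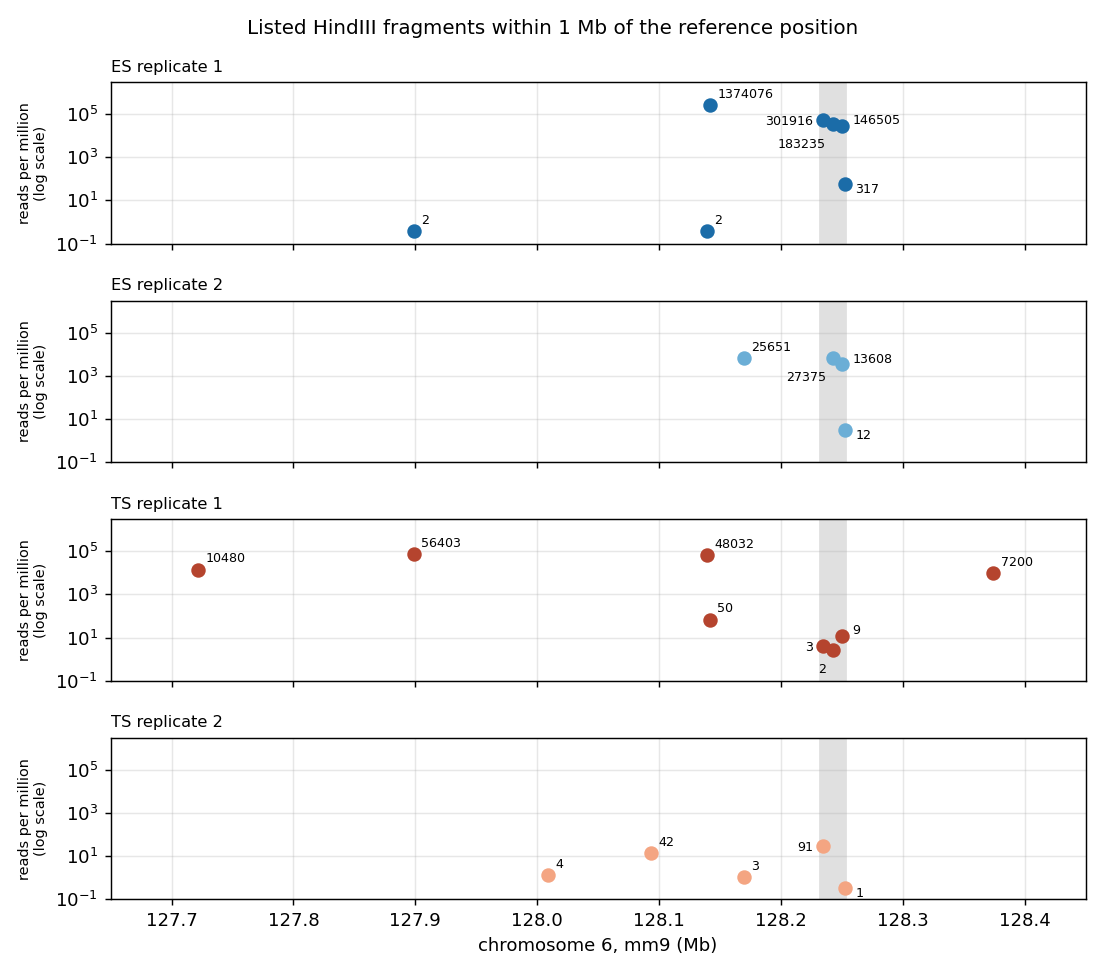
Reads per 1000000 reads of the library (rpm, log scale) of each listed HindIII fragment within 1 Mb of the reference position on chromosome 6 (mm9, Mb), with 1 panel per library, each point 1 fragment labelled with its read count, and the reference stretch shaded. H641130 and H641132, in the shaded stretch, had 13608 to 183235 reads in the ES libraries and 0 to 9 in the TS libraries.

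Listed fragments on other chromosomes were mostly seen in 1 library. Of the 345 fragments outside chromosome 6 and the Y_random contig, 282 were listed in 1 library, 60 in 2, 0 in 3 and 3 in all 4. The 3 in all libraries lie on chromosomes 7 and 11. H690798 (chromosome 7, 148275497 to 148281722) had 896520 and 8016 reads in ES replicates 1 and 2 and 59853 and 1979308 in TS replicates 1 and 2. H125346 (chromosome 11, 69800190 to 69813881) had 367955 and 1014 reads in ES and 312748 and 288304 in TS. H110946 (chromosome 11, 24370069 to 24383802) had 616 and 17 reads in ES and 77 and 3876 in TS, 0.0687 to 0.212% of the H690798 count in each library. In rpm H125346 was at 34581 ± 48546 in ES and 260269 ± 229012 in TS, and H690798 at 84950 ± 117302 in ES and 377945 ± 420226 in TS (SD, n = 2 each). H125346 was higher in both TS libraries than in both ES libraries, and its exact permutation p of 0.333 is the smallest possible, against 0.667 for H690798. edgeR's quasi-likelihood test gave an adjusted p of 0.793 for both. At the estimated dispersion that test called 0 of the 32 simulated 16-fold changes that passed the filter. The adjusted p therefore does not show that the levels were alike.

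Other abundant distal fragments were not abundant in the second library of the same cell type. H393212 (chromosome 19, 52480484 to 52487295) had 194681 reads in TS replicate 1 and 108910 in ES replicate 1, and 0 in both replicate 2 libraries. In ES replicate 1 the leading distal fragments included H649186 (chromosome 7, 7473524 to 7478501) with 955005 reads, H750319 (chromosome 9, 59937229 to 59939121) with 434389 and H436648 (chromosome 2, 125554703 to 125563009) with 364014. In ES replicate 2 they were H445775 (chromosome 2, 153157122 to 153158231) with 3255974, H167266 (chromosome 12, 86428167 to 86430613) with 423093, H650513 (chromosome 7, 11828206 to 11834326) with 167472 and H328638 (chromosome 17, 32288146 to 32291531) with 62209. Each of these 7 had between 1 and 66 reads in the TS library of the same number and 0 in both libraries of the other number. In TS replicate 2, H211826 (chromosome 13, 106463643 to 106464495) had 440437 reads, H035738 (chromosome 1, 112521521 to 112522165) 85916 and H467384 (chromosome 3, 41940313 to 41942167) 34281. H211826 had 1 read in ES replicate 2, and the other two were listed in no other library. In TS replicate 1, H379615 (chromosome 19, 10638691 to 10645180) had 11570 reads and was listed in no other library, and H638133 on chromosome 6 (117909025 to 117910520) had 20544 reads, with 4 in ES replicate 1.

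With every listed fragment counted, the lists overlapped more by replicate number than by cell type. At minimums of 100 and 10000 reads no such order was seen, but the pairs then shared only 0 to 4 fragments, too few to settle an order. ES replicates 1 and 2 shared 7 fragments and TS replicates 1 and 2 shared 4. ES and TS replicate 1 shared 24, and ES and TS replicate 2 shared 53. The pairs that had neither in common shared 6 (ES replicate 1 with TS replicate 2) and 5 (ES replicate 2 with TS replicate 1). All 6 overlaps exceeded the 0.00801 to 0.0338 fragments expected by chance, with adjusted p from 1.23e-155 to 6.71e-10 (Fisher's exact test, one-sided). Of ES replicate 1's list, 6.67% was found in ES replicate 2, against 34.6% of TS replicate 2's list (Fisher's exact test, two-sided, p = 6.87e-08). At 10 reads these shares were 11.3% and 33.3% (Fisher's exact test, p = 0.0624), and at 100 reads 10.5% and 15.4% (Fisher's exact test, p = 0.638). With a minimum of 10 reads in both libraries the counts converged, to 6 for the ES pair, 3 for the TS pair and 6 for each same-number pair. At 100 reads the ES pair shared 4 and the TS pair 2, against 3 for the replicate 1 pair and 2 for the replicate 2 pair. At 10000 reads both cell-type pairs shared 2, against 3 and 0. The 3 fragments listed in every library account for 3 of the 4 shared by the TS libraries. The remaining one is H641127.

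**Figure D2:**
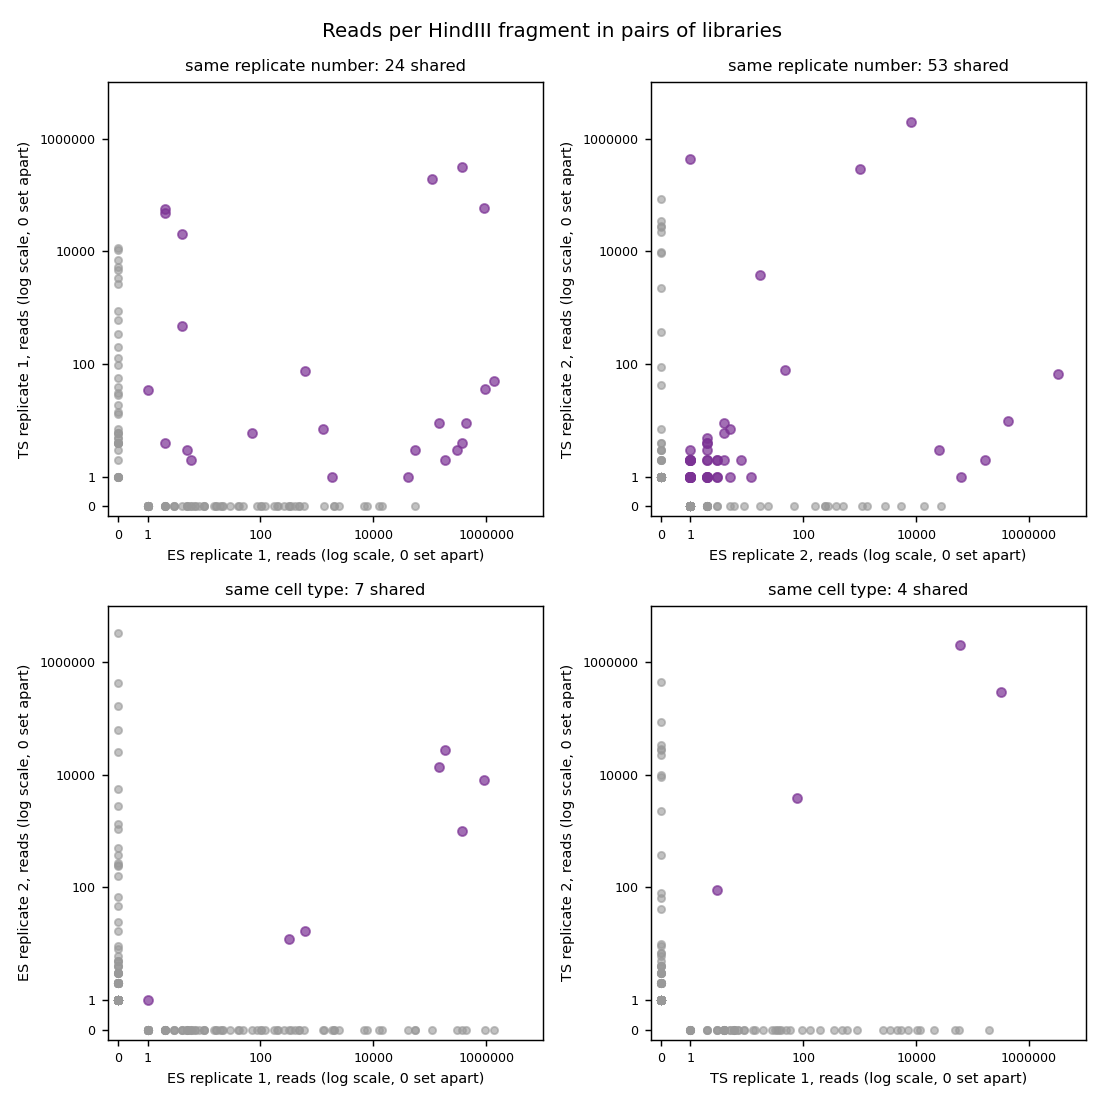
Reads per HindIII fragment in 4 pairs of libraries (log scales, 0 reads set apart), each point 1 fragment, purple where both libraries listed it and grey where 1 did. Same-number pairs shared 24 and 53 fragments, most of them with few reads in at least 1 library, and same-cell-type pairs shared 7 and 4.

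**Figure D3:**
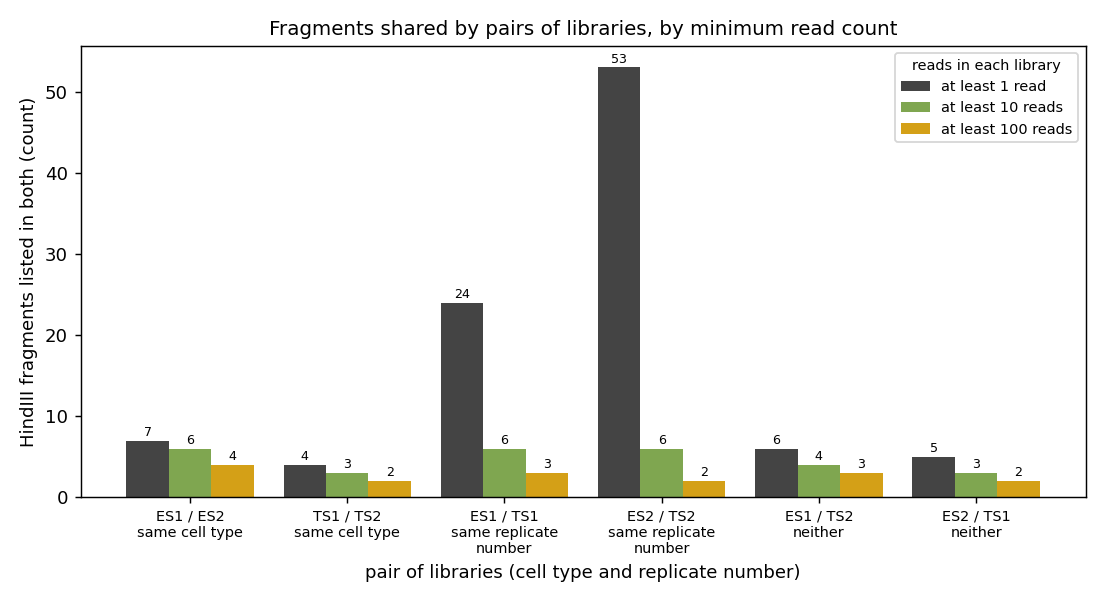
Number of HindIII fragments listed in both libraries of each pair, with a minimum of 1, 10 or 100 reads in each library (ES1 is ES replicate 1, and so on). The same-number pairs drop from 24 and 53 to 6 each at 10 reads, while the ES pair goes from 7 to 6 and the TS pair from 4 to 3.

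No fragment was listed in both TS libraries and in neither ES library, the pattern of a contact specific to TS cells. The mirrored pattern, both ES and neither TS, held for 1 fragment, H186697 (chromosome 13, 28647063 to 28652012), with 1 read in each ES library. That count was 3 without TS replicate 1, where H641130 and H641132 joined it, and 2 without TS replicate 2, where H641133 did. It was 130 without ES replicate 1 and 79 without ES replicate 2, since a single ES library then decides. The split by replicate number gave 18 fragments listed in both replicate 1 libraries alone and 49 in both replicate 2 libraries alone. The count of 0 rests on ES replicate 1 for 1 fragment, H641127, which was in both TS libraries and became the single such fragment without that library. Without TS replicate 1 the count was 98 and without TS replicate 2 it was 40, since a single TS library then decides. When fragments within 100 kb counted as shared, 2 fragments of TS replicate 1 met the pattern, H379615 with 11570 reads and H157538 on chromosome 12 with 13 reads, the latter chosen after its values were seen. The TS replicate 2 fragments that matched them, H379605 and H157510, had 1 read each. A fragment missing from a list was not detected at this depth, which does not show that the contact is absent.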

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

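The minimum counts, the partner-read filter and leaving out Y_random or the fragments listed in every library were chosen after the data were seen. Of 125 values recomputed under alternatives, 78 kept their direction, their side of the threshold and, for counts, stayed within 1.5 times. These 78 include 6 edgeR counts of 0, and the TS minus ES difference in the share on chromosome 6, which was judged on direction alone. All 20 recomputed overlaps within a cell type and all 32 between cell types stayed under an adjusted p of 0.05 in Fisher's exact test, so what moved was the count. The lists themselves shrank with a minimum count. For ES replicates 1 and 2 and TS replicates 1 and 2 they held 50, 64, 31 and 50 fragments above each list's median count, 53, 25, 31 and 18 with at least 10 reads, and 38, 19, 19 and 13 with at least 100 reads. The share on chromosome 6 turned below the background in ES replicate 1 (5.10%) and lost its call in ES replicate 2 (9.39%), TS replicate 1 (14.3%) and TS replicate 2 (8.78%) without the region within 1 Mb of the reference position, and lost its call in ES replicate 1 with the partner-read filter (8.82%). The TS minus ES difference in that share, 6.99 percentage points, ranged from 0.375 (without TS replicate 1) to 13.6 (without TS replicate 2). The ES pair shared 4 fragments, in place of 7, without the 1 Mb region, without chromosome 6, at 100 reads, or without the fragments listed in every library. The TS pair shared 7 within 10 kb, 11 within 100 kb, 2 at 100 reads and 1 without the fragments listed in every library. ES and TS replicate 1 shared 6 above the median count, 6 at 10 reads, 3 at 100 reads and 11 with the partner-read filter. ES and TS replicate 2 shared 21, 6 and 2 under the first 3 of these, and 47 under the filter. ES replicate 1 and TS replicate 2 shared 10 within 100 kb and 3 at 100 reads. ES replicate 2 and TS replicate 1 shared 9 within 100 kb, 2 at 100 reads, and 3 without the 1 Mb region, without chromosome 6, above the median count, at 10 reads or with the partner-read filter. Fragments in both TS and neither ES library numbered 2 within 100 kb and 0 to 98 when 1 library was left out (98 without TS replicate 1, 40 without TS replicate 2, 1 without ES replicate 1), where, without a TS library, the remaining one alone decides. The cause of these shifts was not tested beyond what each construction fixes. edgeR called 0 fragments under every setting run, and DESeq2 called 11. The settings that leave out a library test an arm of 1 sample, assumed to vary like the other arm. At the estimated dispersion edgeR called 0 of the 32 simulated 16-fold changes that passed the filter with 2 libraries per arm. The edgeR counts of 0 therefore show no stability. With the replicate number as a block, edgeR called 0 fragments and the lowest adjusted p was 0.103, against 0.37 without it. Deviations of the same-number libraries correlated at r = 0.633 over the 18 tested fragments, but the labels give only a shared number. Fragments listed only in a same-number pair, such as H436648 and H445775, have deviations of the same sign by construction. The correlation therefore partly restates the sharing and is no separate test. The test of gene lists was not run, because gene positions in mm9 were not used here. TS replicate 1, with 740750 reads, sets the highest detection limit, 4.05 rpm.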

Other observations

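The tests of fragment length, same-number sharing, the Y_random lengths and H110946 were chosen after the values had been seen, and the gene density test before its correlation was computed, although the many entries on chromosome 11 had been noticed. Chromosomes with more protein-coding genes per HindIII fragment held more listed fragments per HindIII fragment. Over the 19 chromosomes other than chromosome 6, Spearman's rho was 0.616 (one-sided permutation p = 0.00291, adjusted p = 0.00437 over 3 relations) and Pearson's r was 0.666 (p = 0.00089), falling to 0.523 without chromosomes 7 and 11. Gene counts per chromosome came from the GRCm38 table, and chromosomes are not independent replicates. Both values were divided by the same count of HindIII fragments, and a shared divisor can by itself give a positive correlation. Fragment length per chromosome was not taken into account. Chromosome 11 had 82.8 listed fragments per 100000 and the X chromosome 16.9. The relation was seen in the replicate 2 libraries (rho 0.639, p = 0.00188, adjusted p = 0.00437) and did not pass in the replicate 1 libraries (rho 0.246, p = 0.153). The difference between the 2 was not tested.

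Listed fragments were long. Their median length outside chromosome 6 and Y_random was 4998 bp (n = 345) against 2136 bp for the background, and the permutation p of 1e-05 is the smallest that 100000 random lists can give. The median was 5093 bp for fragments with under 10 reads in each library and 4979 bp for those with at least 100 reads in a library. A draw weighted by length, from fragments no longer than the longest listed one (24645 bp), would have a median of 5296 bp. That limit was taken from these same data. When random lists were drawn with that weight and limit, 200 draws per pair gave at most 1 shared fragment. Length weighted in this way therefore does not account for the 4 to 53 fragments shared by the pairs.

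Libraries of the same replicate number shared more fragments than libraries of the same cell type when every listed fragment counted, but at 10 reads the ES pair shared as many (6 against 6 and 6) and at 100 reads more (4 against 3 and 2), with 3 and 2 for the TS pair. A single pool of contacts sampled alike by every library is not excluded among fragments of at least 100 reads. There 10.5% (4 of 38) of ES replicate 1's list and 15.4% (2 of 13) of TS replicate 2's were found in ES replicate 2 (Fisher's exact test, p = 0.638). In the full lists these shares were unequal (Fisher's exact test, p = 6.871e-08), also with the partner-read filter (6.86% and 31.8%, Fisher's exact test, p = 1.54e-06). That difference is the sharing pattern itself, carried mostly by fragments with few reads, so it leaves the abundant fragments undecided. Carry-over of reads between same-number libraries is a candidate explanation for part of the same-number sharing. Of entries of a fragment at 10000 or more reads in a library, 47.37% (18 of 38) were listed at under 1 in 1000 of that count in the same-number library. In the other-number libraries it was 3.95% (3 of 76; Fisher's exact test, p = 5.73e-08, with fragments counted more than once). The 47.37% missed the bound of more than 50% set for carry-over. Entries abundant in both same-number libraries, such as H690798 in replicate 1 (896520 and 59853 reads in ES and TS), cannot count as listed low. The missed bound therefore does not argue against carry-over. The minimum was then raised to 100000 reads, after that result, because 10000 reads at the median ratio of 23.99 per 1000000 give under 1 read, and the share became 61.1% (11 of 18) against 2.78% (1 of 36; Fisher's exact test, p = 3.39e-06), so carry-over stays open and is not settled by the second threshold. As the source of most sharing it is argued against in replicate 2. At the highest ratio of 194.7 per 1000000, few shared fragments had enough reads in 1 library to give 1 read in the other. The share was 15.09% (8 of 53, exact 95% interval 6.75 to 27.6%). That ratio is the highest among the 18 entries above, which the rule of under 1 in 1000 selected. Of the 53 fragments, 42 had under 10 reads in both libraries, too few to give 1 read even at 1 in 1000. Carry-over stays open in replicate 1, with 62.5% (15 of 24, 40.6 to 81.2%). None of the 42 replicate 2 fragments with under 10 reads in both libraries was listed in a replicate 1 library, and a source common to both replicate 2 libraries, or contacts common to ES and TS cells in those libraries, stay open and were not tested.

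ES replicate 1 alone listed Y_random fragments, 26 of them with 58613 reads, against 0 in ES replicate 2 and in both TS libraries. Reads from 1 ligation product spread over near-identical repeat copies may account for the list. Of the 26, 30.77% had a length found in 50 or more fragments of the contig, against 12.3% of all its fragments (Fisher's exact test, p = 0.0103), which is above the contig but short of the 50% set for that explanation. In a length range chosen after the values were seen, 920 to 970 bp, lay 24 of the 26 and 1.70% of the contig, and 1 fragment held 92.2% of the contig's reads. Repeat copies and separate contacts cannot be told apart without the sequences, and no biological explanation was tested.

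H110946 on chromosome 11 followed H690798 on chromosome 7 across libraries. The ratio of their reads stayed between 0.0687 and 0.212%, a 3.09-fold range, while H690798 itself varied 247-fold. No other pairing of the libraries gave a smaller spread (exact one-sided p = 0.04167, the smallest of 24 pairings), whereas the ratio to H125346 varied 68.1-fold (p = 0.167). The pairing test ranks the spread and cannot show that the share is fixed. The share was 0.0687% in ES replicate 1 (616 reads of H110946) and 0.196% in TS replicate 2 (3876 reads). Reads here are not independent molecules, and no error of these shares was estimated. An equal share in every library was therefore neither shown nor excluded. Assignment of a share of H690798 reads that differed between libraries to a similar sequence in H110946 stays open. A joint contact of both regions also stays open, and neither was tested.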
